A study of Mus musculus with 22 samples.

How the data were processed

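Per the labels, the material was crosslinked chromatin of small intestinal crypts of C57BL/6 mice and of E14 embryonic stem cells (ESC), and each peak list came from 1 library. The submitters' processing notes name Bowtie 1.2.2 and 1.1.2, MACS2 2.1.1 and the builds mm10, dm6 and hg38, without giving the role of each. Other settings of the aligner and the peak caller were not given in the sources used here. Peaks were called per sample, with the WT input named as the reference. The deposited scores are −log10 p values that the authors' peak caller computed for each peak, and whether p or q is meant was not stated. All scores were 10 or more. The 6 input samples have no list and were not used here. H2AK119ub1 chromatin had 5% Drosophila S2 chromatin added, and no spike count was used here.

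The lists were used as deposited, with chromosomes 1 to 19, X and Y kept. BED starts were converted to 1-based positions. A WT peak was matched when at least 1 bp overlapped a KO peak of the same antibody and Cre line. Chance overlap was the mean of 100 shuffles within chromosomes, with starts after the first 3000000 bp. Shares have exact Clopper-Pearson 95% intervals. Peaks at PCGF6 sites and elsewhere were compared for loss by two-sided Fisher's exact tests, with sample odds ratios, adjusted by Benjamini-Hochberg over 6 tests, and at equal score by Mantel-Haenszel odds ratios over 5 or 20 score strata. Odds ratios of the Cre lines were compared by Woolf's chi-square test over 4 tests. These designs, the 16 gene lists, the alternatives and the rule for naming genes were chosen before the data were examined, apart from the additions named below.

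Genes were the 21887 protein-coding genes of the mm10 table, which gives no strand and no transcript starts. A window of 1 kb around either gene end therefore replaced the intended promoter window. A gene counted as lost when a WT peak lay in its window, no KO peak did, and no WT peak there overlapped any KO peak. The last condition was added after seeing the data, because a peak that narrows past the window is not lost, and gains were counted likewise. Gene lists were tested against all other genes by two-sided Fisher's exact tests, and lost genes against genes with a WT peak, adjusted over 336 tests. Crypt and ESC lists were compared by the exact McNemar test over 32 tests. Named genes were the 10 with the highest scores among lost and among gained genes, for RING1B and H2AK119ub1 in both Cre lines by mean score rank, the 10 highest PCGF6 genes shared and not shared with ESC or RING1B, members of the gene lists, and Pcgf6. Some genes that this rule names are not reported here.

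In the description lines of the ESC samples, 1 line exchanges the names PCGF6 and RING1B. The titles, the antibody tags and the second line were used. As a check, all 39 Hox genes had a peak in the list titled RING1B. Overlap counts were checked against bedtools and differed in 0 of 4 pairs. All 200 peaks removed from a copy of a list were found. On simulated losses, Mantel-Haenszel odds ratios averaged 0.993, 1.98 and 4.02 for true values of 1, 2 and 4, and 1 of 800 tests of random gene lists passed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and bedtools 2.31.1 were used.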

Results

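ChIP-seq peaks were compared between crypts of wild-type (WT) mice and of mice with induced, Cre-driven loss of Pcgf6 (knockout, KO), with embryonic stem cells (ESC) beside them. KO thus does not mean mice that lacked the gene throughout life. AhCre and Villin samples have the same time since induction, but whether it holds for the ChIP crypts was not stated. Whether the results depend on that time was not tested. Crypts are the stem cell-bearing pits of the small intestinal epithelium. PCGF6 is a Polycomb RING finger protein of a variant PRC1 complex, RING1B is the ubiquitin ligase subunit of PRC1, and H2AK119ub1 is the histone mark that PRC1 places. CTCF is a DNA-binding insulator protein and RAD21 is a subunit of the cohesin ring. The series had 22 samples, of which 16 had a peak list and 6 were input samples without one. In the AhCre line, PCGF6, RING1B and H2AK119ub1 were profiled in each genotype. In the Villin-Cre line these were RING1B, H2AK119ub1, CTCF and RAD21. WT ESC of the E14 line were profiled for PCGF6 and RING1B. Every group had 1 library, so no value has a replicate error, and each p describes the peaks or genes of the lists rather than mice. Neighbouring genes can share 1 peak (the widest covered 62298 bp), and the tests count them as separate genes. The lists hold no read counts, so the depth of each library is unknown. They held between 1662 and 32651 peaks, each with a score of 10 or more (−log10 p or q, which of them was not stated). A gene is said to have a peak when a peak lay within 1 kb of either of its ends, and to have lost it when no WT peak there overlapped a KO peak and no KO peak lay there. The ends of a gene were not told apart, so such a peak need not lie at its promoter. Positions are 1-based on mm10.

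The PCGF6 comparison asked where PCGF6 sits in adult crypts and how much of that signal goes with the gene. PCGF6 peaks lay at 8740 of 21887 protein-coding genes in WT AhCre crypts and at 2990 in KO crypts. Peaks were lost at 5631 genes and gained at 20. The strongest lost peak was that of Nmi (chromosome 2, 51972536 to 51973853, score 260). It was followed by Cdca7l (score 137), Pthlh, which encodes parathyroid hormone-related protein (score 106), Afap1l1 and Nptx2 (score 102). P2rx2, Smc5, the growth factor gene Bmp7, Fam221a and the topoisomerase gene Top2a completed the 10 strongest, with scores from 98.8 down to 82.0. The 10 strongest gained genes all had weak KO peaks, from Eif2s3x (score 16.3) and E2f4 (score 15.4) through Zfyve1, Atp2b1, Ctbp1, Ddx54 and Rita1 to Etnk2, Mid1ip1 and Ppp2r5c (score 11.1 each). Ddx54 and Rita1 shared 1 peak. At Pcgf6 itself, a WT PCGF6 peak of score 20.8 (chromosome 19, 47050342 to 47051479) had no KO counterpart.

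Among the 16 gene lists, ribosomal protein genes, cell cycle genes and genes of PRC1 had PCGF6 most often. Of 75 cytosolic ribosomal protein genes, 70 had a WT peak, among them Rps29 (score 212 in WT, 60.0 in KO) and Rpl13a (133 and 55.6). The odds ratio against all other genes was 21.2 (adjusted p = 1.41e-21, Fisher's exact test). Of 45 replication and cell cycle targets of E2F, 36 had a peak, such as the sliding clamp gene Pcna (164 and 42.0) and the ubiquitin-linked Uhrf1 (59.0 and 22.0), with an odds ratio of 6.04 (adjusted p = 3.69e-07, Fisher's exact test). Genes for PRC1 and its partners had a peak in 29 of 37 cases, with an odds ratio of 5.47 (adjusted p = 1.54e-05, Fisher's exact test). Mga (1180 and 325), Tfdp1 (318 and 82.5), Hdac2 (313 and 75.7) and E2f6 (254 and 37.5) were the strongest of these. The KO list was also enriched at ribosomal protein genes (35 of 75, odds ratio 5.58, adjusted p = 4.23e-11) and E2F targets (13 of 45, 2.57, adjusted p = 0.0270), by Fisher's exact test. WT PCGF6 peaks were less frequent than at other genes in Hox genes (5 of 39, adjusted p = 0.00234), in other developmental transcription factors (17 of 126, adjusted p = 8.18e-10) and in mesenchymal and endothelial markers (2 of 18, adjusted p = 0.0479), each by Fisher's exact test. The same test gave an adjusted p of 2.19e-249 for olfactory receptors (1 of 1110) and 1.36e-10 for clustered protocadherins (1 of 57).

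No list of intestinal cell type markers passed the test for having a PCGF6 peak more or less often than other genes. The lists held 10 to 26 genes, so differences are not excluded. Shares ran from 10% (Paneth) to 64.7% (stem cell markers), against 39.9% of other genes. In WT crypts a peak was present at 8 of 26 tuft cell markers, 11 of 17 stem cell markers, 1 of 10 Paneth cell markers, 4 of 12 goblet cell markers, 4 of 22 enteroendocrine markers and 10 of 20 enterocyte markers (lowest adjusted p = 0.142, Fisher's exact test). Germline and meiosis genes had one in 18 of 63 cases (adjusted p = 0.187) and immune cell markers in 4 of 19 (adjusted p = 0.247), by Fisher's exact test. Over all genes, 5631 of 8740 with a WT peak lost it. No list of intestinal markers passed the test for a different share lost (lowest adjusted p = 0.541, Fisher's exact test). Peaks were lost at 6 tuft cell markers, including the tuft cell regulator Pou2f3 (score 14.3), Spib (32.2), Ltc4s (49.6) and Ascl2 (67.7), while Sh2d6 had a peak in both genotypes (106 and 28.2). Ascl2 is also a stem cell marker, and among the 7 stem cell markers with a lost peak were Lgr5 (18.9), Tert (24.4) and Smoc2 (12.3). The enterocyte regulators Cdx2 (12.6), Hnf4a (12.4), Hnf4g and Klf4 (32.2) were among 7 enterocyte markers that lost their peak, and Cdx1, Vil1 and Fabp2 had one in both genotypes. Losses at the other lineages included Atoh1, Agr2, Ccl9 and Fcgbp (goblet), Insm1, Gip and Sct (enteroendocrine) and Dll4 (Paneth).

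Loss of the PCGF6 peak differed between groups of genes, in tests not made at equal score although weak peaks were lost more often than strong ones. Among genes with a WT peak, 16 of 17 developmental transcription factors outside the Hox clusters lost it, among them Tbx1, Olig1, Foxa2 and Gata5, against 64.4% of other genes (odds ratio 8.86, adjusted p = 0.0338, Fisher's exact test). Ribosomal protein genes lost it less often, in 34 of 70 cases against 64.6% (odds ratio 0.519, adjusted p = 0.0291, Fisher's exact test). All 5 Hox genes with a peak lost it (Hoxa4, Hoxa5, Hoxa6, Hoxd1 and Hoxd4), which did not pass the test (adjusted p = 0.351, Fisher's exact test). In the germline list, Zcwpw1 (902 in WT, 112 in KO), Tdrkh (466 and 56.2) and Syce2 (189 and 35.8) had peaks in both genotypes, and 11 genes such as Mei1, Rad51c and Tex14 lost theirs. Scores are not scaled between libraries, so a lower KO score is a value of each list and not a tested change.

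Over all peaks, the WT list held 17163 PCGF6 peaks and the KO list 4779. Of the WT peaks, 26.9% (exact 95% interval 26.2 to 27.6) overlapped a KO peak, against a mean of 0.427% after shuffling. Only 83 KO peaks had no WT counterpart. The peaks that were lost were mostly weak. Their median score was 15.2 against 38.8 for those found in both lists, and the share lost ran from 97.7% in the weakest score decile of WT peaks to 8.33% in the strongest. With both lists shortened to the 4779 strongest peaks, 1513 were found only in WT and 1446 only in KO. Such lists are of equal length by construction, so only unequal lists can show a net loss. Intervals of shares cover counting error only.

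**Figure D1:**
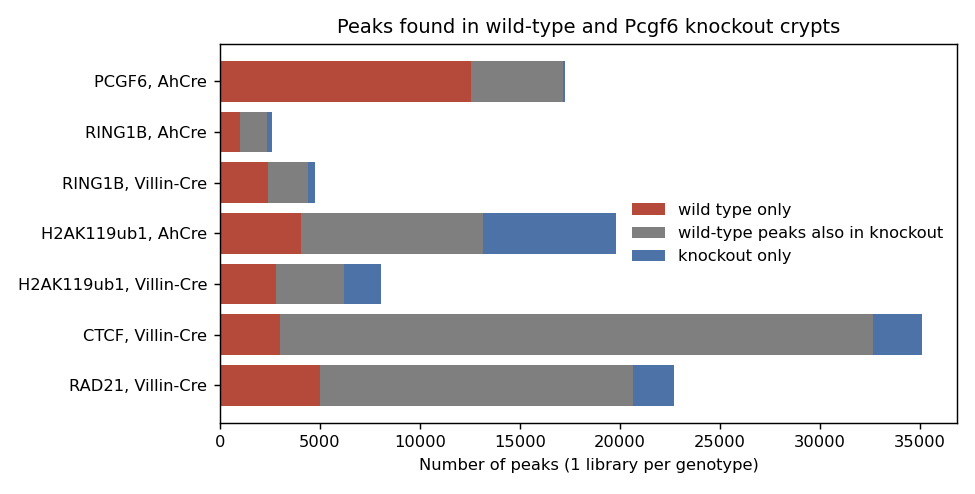
Number of peaks (horizontal axis) per antibody and Cre line, with 1 library per genotype: WT peaks without a KO peak (red), WT peaks that overlap a KO peak (grey) and KO peaks without a WT peak (blue). PCGF6 in AhCre crypts has 12545 WT-only peaks and 83 KO-only peaks, and H2AK119ub1 in AhCre crypts has 6629 KO-only peaks.

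**Figure D2:**
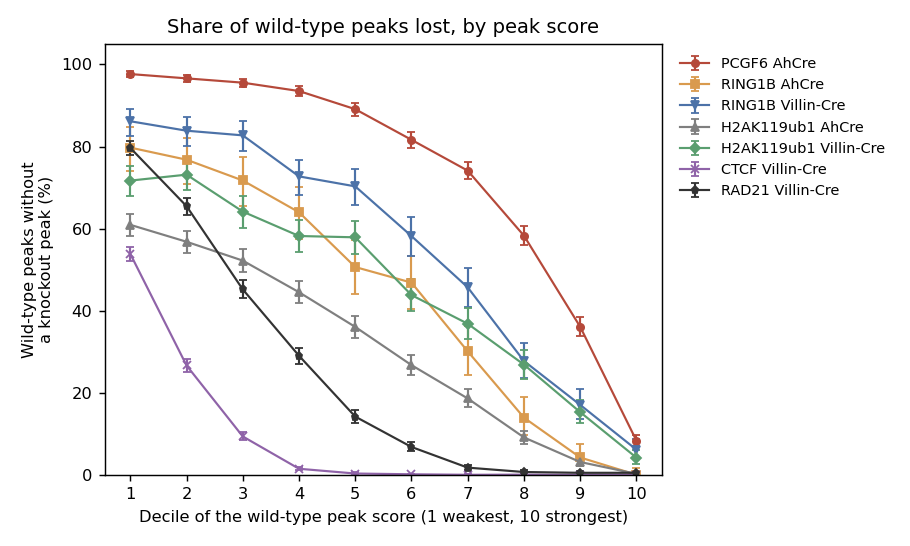
Share of WT peaks without a KO peak (vertical axis, percent) by decile of the WT peak score, from the weakest (1) to the strongest (10), for each antibody and Cre line; bars are exact 95% intervals for counting error. PCGF6 runs from 97.7% to 8.33% and CTCF from 53.8% to 0.

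RING1B peaks were examined in both Cre lines, which gives the same contrast in separate experiments. RING1B lay at 1693 genes in AhCre WT crypts and 3112 in Villin WT crypts. Its peaks were lost at 757 and 1670 genes and gained at 158 and 246. Of 1452 genes with a WT peak in both lines, 271 lost it in both, against 139.8 if the lines were independent. The odds ratio was 8.30 without regard to score (p = 7.91e-60, Fisher's exact test). Ranked by score over both lines, the genes lost in both were led by the mitochondrial calcium uptake gene Micu2 (chromosome 14, score 42.0 in AhCre and 135 in Villin). Next was the ubiquitin ligase adaptor gene Spop (chromosome 11, 34.8 and 76.5). Dhx40 (32.5 and 83.5), Tmem80, Trim44, the imprinted receptor gene Igf2r, Ccdc183, Rabl6, Zfp280d and the histone demethylase gene Kdm3a followed, with AhCre scores from 18.2 to 32.5. Ccdc183 and Rabl6 shared 1 peak. Gains in both lines were few and weak. The 11 genes included Ubr4 (19.4 and 17.1), Cblb, Sdc3, Atp6v0b, Csgalnact1, Ptpn18, Tln2 and Pias3, and the neighbours Cacnb1 and Rpl19 with 1 peak between them.

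Developmental genes were the gene groups with RING1B most often, and most had it in both genotypes. Hox genes had RING1B in 33 of 39 cases in both genotypes of AhCre crypts and in 34 (WT) and 33 (KO) in Villin crypts, where Hoxd4 was the gene lost. The odds ratio in AhCre WT crypts was 66.9 (adjusted p = 3.61e-30, Fisher's exact test). Other developmental transcription factors had it in 85 of 126 cases (AhCre WT, odds ratio 26.0, adjusted p = 1.24e-62, Fisher's exact test), among them Otx1 (825 in WT, 703 in KO), Onecut2 (348 and 225) and Dlx1 (318 and 282). In Villin crypts 97 of these factors had RING1B in WT, of which 82 had it in both genotypes and 13 lost it, such as Dlx5 (25.8), Barhl1 (21.9) and Six3 (21.9). Of genes with a WT peak in both lines, and not at equal score, 0 of 33 Hox genes lost it in both, against 271 genes outside the list that did (adjusted p = 0.0104), and 1 of 85 developmental transcription factors did, Mnx1, against 19.8% (odds ratio 0.0484, adjusted p = 3.09e-06), by Fisher's exact test. Enteroendocrine markers were also enriched (7 of 22 in AhCre WT crypts, odds ratio 5.59, adjusted p = 0.00519, Fisher's exact test). Pax6 (199 and 133), Neurod2 (132 and 109) and Insm1 (65.0 and 66.6) had peaks in both genotypes, as did the goblet cell regulators Atoh1 (147 and 127) and Gfi1 (102 and 181).

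RING1B losses in Villin crypts were also found in other lists, and the shares lost there were not tested. Over all genes, 1670 of 3112 with a WT peak lost it. Genes of PRC1 and its partners had RING1B in 19 of 37 cases in Villin WT crypts (odds ratio 6.40, adjusted p = 7.42e-07, Fisher's exact test), and 10 of them lost it. Tfdp1 (45.3), Hdac2 (35.2), E2f6 (34.8) and Ezh2 (19.5) had the strongest of these WT peaks. Mga had RING1B in both genotypes of both lines, with scores of 86.8 and 20.4 in AhCre crypts and 130 and 23.6 in Villin crypts. Of 11 ribosomal protein genes with RING1B in Villin WT crypts, 10 lost it, including Rpsa, Rpl12 and Rps18. E2F targets with a lost peak in Villin crypts were Msh6, Ccne1, E2f8, Cdt1 and Mybl2, and no E2F target had RING1B in both genotypes there. List members that lost RING1B in both lines were Ltc4s, Tert, Meiob, Hdac2, Mnx1, E2f8 and Rpsa.

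At the level of peaks, RING1B numbered 2368 in AhCre WT and 1662 in KO crypts, and 4403 and 2464 in Villin crypts. KO peaks overlapped 56.2% of AhCre WT peaks (exact 95% interval 54.2 to 58.2) and 44.9% of Villin WT peaks (43.5 to 46.4). KO-only peaks numbered 266 and 370. Among 2053 Villin WT peaks that also overlapped an AhCre WT peak, 358 were lost in both lines against 187 if independent (odds ratio 6.49, 95% interval 5.24 to 8.05, p = 2.14e-70, Fisher's exact test). At equal Villin WT peak score this odds ratio was 3.32 (Mantel-Haenszel), with the AhCre score not held equal. With lists of equal length the WT-only and KO-only counts were 502 and 432 in AhCre and 861 and 730 in Villin crypts.

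H2AK119ub1 covered all 39 Hox genes in both genotypes of AhCre crypts, and 38 in WT and 36 in KO Villin crypts, where Hoxb1 and Hoxc4 lost it. Other developmental transcription factors had the mark in 98 (WT) and 107 (KO) of 126 cases in AhCre crypts and in 93 and 88 in Villin crypts. Their odds ratio against other genes was 18.8 in AhCre WT crypts (adjusted p = 5.10e-52, Fisher's exact test) and 25.4 in Villin WT crypts (adjusted p = 9.70e-63, Fisher's exact test). Examples are Pax3 (77.8 in WT, 63.2 in KO), Nkx2-3 (75.6 and 83.5) and Lhx2 (65.9 and 73.5) in AhCre crypts. Stem cell markers were enriched in AhCre WT crypts (8 of 17, odds ratio 4.66, adjusted p = 0.0121, Fisher's exact test), and Lgr5, Ascl2 (22.6 and 35.9) and Slc12a2 (18.2 and 25.1) had the mark in both genotypes. Ribosomal protein genes were depleted (3 of 75, odds ratio 0.217, adjusted p = 0.0107, Fisher's exact test). Mesenchymal and endothelial markers, of other cell types, were enriched in Villin WT crypts (7 of 18, odds ratio 5.52, adjusted p = 0.00722, Fisher's exact test). In AhCre WT crypts these markers did not pass the test (6 of 18, odds ratio 2.62, adjusted p = 0.160, Fisher's exact test). In AhCre crypts the mark was gained at 11 developmental factors, among them Dlx5 (28.0), Six6 (20.5) and Cdx4 (17.0), and lost at Six3 and Vsx1. In Villin crypts 7 such genes lost it, among them Zic1, Zic4, Pax5 and Mnx1, and En1, Sox11 and Tbx4 gained it.

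The loci where H2AK119ub1 changed status in both lines were few. Of 2055 genes marked in WT crypts of both lines, 37 lost the mark in both against 9.73 if independent. The odds ratio was 41.3 without regard to score (p = 3.17e-20, Fisher's exact test), and 46 genes gained the mark in both lines. The strongest lost genes were Mfge8 (15.6 in AhCre, 13.4 in Villin), the telomerase gene Tert (15.3 and 11.2), Rundc3a, Fancf, Gas2, Ssh3, Grm6, Plpp4, Neto2 and Gde1. Fancf and Gas2 shared 1 peak. The strongest gained genes were Dlg3 (38.2 and 12.4), the phosphate transporter gene Slc34a2 (26.1 and 14.3), Csnk1e, Trem2, Aldh1l2, Ripply1, the smooth muscle myosin gene Myh11, Septin10 with Sowahc at 1 peak, and Lin28b. Tert lost RING1B in both lines as well, and Mga, of the PRC1 list, also lost H2AK119ub1 in both.

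Peak numbers of H2AK119ub1 went opposite ways in the Cre lines. AhCre crypts had 13175 peaks in WT and 16039 in KO (ratio 1.22), and Villin crypts had 6219 and 5492 (ratio 0.883). In AhCre crypts 4061 peaks were WT-only and 6629 KO-only, and in Villin crypts 2811 and 1859. With lists of equal length these counts were 4798 and 4642 in AhCre and 2270 and 2021 in Villin crypts, near equal by construction. The share of WT peaks that overlapped a KO peak was 69.2% (exact 95% interval 68.4 to 70.0) in AhCre and 54.8% (53.6 to 56.0) in Villin crypts. Both H2AK119ub1 sets came from chromatin spiked with 5% Drosophila S2 chromatin, but peak numbers and scores are not spike-scaled as far as the lists show. Among 5279 Villin WT peaks that overlapped an AhCre WT peak, 171 were lost in both lines against 68.9 if independent. The odds ratio was 23.9 (95% interval 13.6 to 42.2, p = 1.07e-58, Fisher's exact test). At equal Villin WT score it was 13.7 (Mantel-Haenszel), with the AhCre score not held equal.

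CTCF had 32651 WT and 32143 KO peaks in Villin crypts, and 90.8% of the WT peaks (exact 95% interval 90.5 to 91.1) and 92.3% of the KO peaks (92.0 to 92.6) had a counterpart. It lay at 43 of 75 ribosomal protein genes (odds ratio 3.95, adjusted p = 3.93e-08) and 24 of 57 clustered protocadherins, whose promoter choice uses CTCF (odds ratio 2.13, adjusted p = 0.0226), by Fisher's exact test. Rps29 (328 in WT, 329 in KO) and Rplp0 (328 and 245) had it in both genotypes, and Rpl8, Rpl9 and Rplp2 lost weak peaks. CTCF was lost at 670 genes and gained at 205. The strongest lost peaks were at the chromatin gene Setd5 (65.5), Fignl1 (51.9), the histone chaperone gene Asf1a (48.9), Actg2, Ttpal, Mfhas1, Adgrf1, Adpgk and the neighbours Slc47a1 and Slc47a2. The strongest gained peaks included those at Slitrk6 (31.9), Bnip5 (31.5), Mpv17l2 and Rab3a at 1 peak (29.2), Rps6ka4, the fucosyltransferase gene Fut2, Cma1, Vsnl1 and Gm12657. Developmental transcription factors lost CTCF in 7 of 24 cases (Evx2, Foxl2, Irx5, Pax1, Sox11, Sox21 and Tlx3) against 11.9% of other genes, which did not pass the test (odds ratio 3.04, adjusted p = 0.0648, Fisher's exact test). Lgr5 and Tert were the stem cell markers that lost CTCF. Differences sat among weak peaks: of WT peaks in the strongest decile, 0 of 3265 were lost (exact upper bound 0.113%). Above the median score 5 WT-only and 6 KO-only peaks remained.

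RAD21 peaks were lost at 2000 of 4866 genes and gained at 276. The strongest lost peak covered the overlapping ends of Atl1 and Map4k5 (chromosome 12, 69892475 to 69893516, score 162), and the next were at Tpbgl (102), Fam3c (94.6), the phosphatase gene Ptpn2 (92.9), Fbxo34 (76.1), Sdk1, Synm, Dapk2 and Cep135. Gains were led by Slc6a11 (46.9), Eci2 (35.3), the oestrogen receptor gene Esr2 (31.4) and Rpl19 (31.4), followed by Map1lc3b with Zcchc14 at 1 peak, Fcho1, Ccdc24, Pgam5 and Clpsl2. RAD21 was lost at 12 of 24 ribosomal protein genes that had it, such as Rpl7 (37.3) and Rpl36 (19.7), and at 7 of 11 genes of PRC1 and its partners (among them Cbx2, Cbx8, E2f6, Pcgf5, Pcgf6 and Wdr5). Neither share passed the test against that of other genes (adjusted p = 0.633 and 0.295, Fisher's exact test), and with so few genes a difference is not excluded. Enterocyte markers had RAD21 in 8 of 20 cases in each genotype, which passed the test in KO crypts, where 3058 other genes had it (odds ratio 4.10, adjusted p = 0.0161), and not in WT crypts, where 4858 did (2.33, adjusted p = 0.170), by Fisher's exact test. Among them were Klf4 (56.7 in WT, 35.5 in KO), Elf3 (55.8 and 42.4) and Vil1 (22.4 and 73.0).

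RAD21 peaks numbered 20653 in WT and 17762 in KO crypts, with 5033 WT-only (24.4%) and 2038 KO-only. With lists of equal length 2806 were WT-only and 2692 KO-only. The share of RAD21 peaks with a CTCF peak of the same genotype was 87.2% (exact 95% interval 86.7 to 87.6) in WT and 93.5% (93.1 to 93.9) in KO crypts. The odds ratio of KO to WT was 2.12 (95% interval 1.97 to 2.28, p = 1.97e-98, Fisher's exact test). This test took the lists as independent, although 15620 WT peaks overlapped a KO peak. It was not made at equal score, and WT peaks without CTCF were weaker (median score 12.8 against 34.5 with it). Among RAD21 peaks above their list's median score, 99.5% of WT and 99.9% of KO peaks had CTCF. The odds ratio there was 6.77 (2.89 to 15.8), resting on 47 of 10330 WT and 6 of 8887 KO peaks without CTCF.

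Loss of the other factors was then compared with PCGF6 occupancy, to ask whether it was tied to where PCGF6 sits. The sites were the 12545 WT PCGF6 peaks absent from the KO list, and peaks elsewhere include those on PCGF6 peaks also found in the KO list. PCGF6 was profiled in AhCre crypts only, so the tests in Villin crypts used sites of the other Cre line. RAD21 was lost at 36.6% of its WT peaks on these sites against 21.6% elsewhere (odds ratio 2.104, 95% interval 1.95 to 2.27, adjusted p = 7.86e-80), and CTCF at 11.4% against 8.89% (1.32, 1.18 to 1.47, adjusted p = 2.04e-06), by Fisher's exact test. H2AK119ub1 was lost less often on the sites than elsewhere in both lines, at 16.2% against 33.1% in AhCre (odds ratio 0.391, adjusted p = 1.18e-51) and at 37.5% against 46.9% in Villin crypts (0.681, adjusted p = 2.24e-08), by Fisher's exact test. RING1B loss showed no difference past the test in AhCre crypts, at 45.0% against 43.2% (odds ratio 1.08, 95% interval 0.905 to 1.28, adjusted p = 0.428), and was less frequent on the sites in Villin crypts, at 52.6% against 56.3% (0.863, 0.760 to 0.979, adjusted p = 0.0265), by Fisher's exact test. These 6 tests form 1 family. They were two-sided.

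For RING1B this answer depended on the peaks used for comparison. Against RING1B peaks without any PCGF6 peak, a comparison chosen after seeing the data, loss was more frequent on the sites in both lines, at 45.4% against 35.9% in AhCre (odds ratio 1.49, 95% interval 1.23 to 1.80, adjusted p = 3.40e-05) and 52.7% against 41.9% in Villin crypts (1.55, 1.34 to 1.79, adjusted p = 3.20e-09), by Fisher's exact test. At equal peak score these odds ratios were 1.38 and 1.28 (Mantel-Haenszel), whereas the planned comparison with all peaks elsewhere gave 0.998 and 0.649 (95% interval 0.557 to 0.757) for RING1B. Against peaks without PCGF6 at equal score, the odds ratios of H2AK119ub1 were 0.612 and 0.906, and that of CTCF was 2.08. With all 17163 WT PCGF6 peaks, RING1B was lost more often at PCGF6 in both lines, with odds ratios of 1.87 in AhCre (adjusted p = 9.27e-14) and 2.37 in Villin crypts (adjusted p = 5.07e-42), by Fisher's exact test. On PCGF6 peaks also present in the KO list, a class set apart after seeing the data, 60.9% of RING1B peaks were lost in AhCre and 74.3% in Villin crypts. Matching overlaps within 1 kb gave 0.891 for Villin crypts (adjusted p = 0.0811, Fisher's exact test). At equal peak score the H2AK119ub1 odds ratio was 0.602 instead of 0.391 in AhCre crypts, and 0.871 in Villin crypts with a 95% interval of 0.751 to 1.012 that included 1 (Mantel-Haenszel). With all PCGF6 peaks at equal score, a setting chosen after seeing the data, these were 0.751 and 1.03, and that of CTCF was 2.18. With CTCF peaks above the median score the odds ratio was 1.48 on 5 lost peaks (adjusted p = 0.579, Fisher's exact test).

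**Figure D3:**
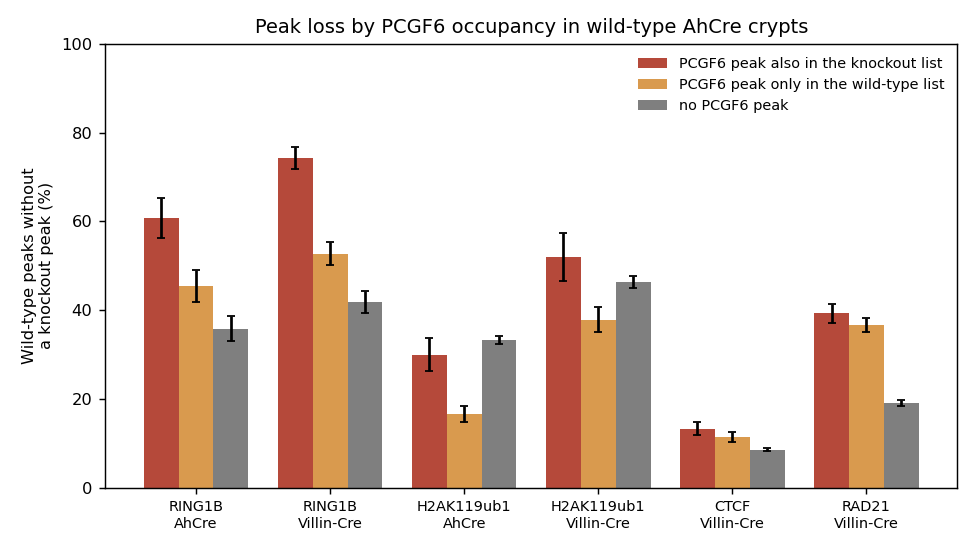
Share of WT peaks without a KO peak (vertical axis, percent) for RING1B, H2AK119ub1, CTCF and RAD21, split by whether the peak overlaps a PCGF6 peak also in the KO list (red), only a PCGF6 peak of the WT list (orange) or none (grey); bars are exact 95% intervals for counting error, with 1 library per genotype. RING1B loss in Villin crypts is 74.3%, 52.7% and 41.9% in these classes. The PCGF6 lists are from AhCre crypts.

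Genes with PCGF6 sites carried the other factors more often than other genes in WT crypts. The other genes include those whose PCGF6 peaks were all in the KO list too. RING1B was at 11.7% against 6.29% of genes in AhCre and 21.5% against 11.5% in Villin crypts. Peaks at opposite ends of a gene count as shared. By peak, 6.29% of WT-only PCGF6 peaks overlapped AhCre WT RING1B and 11.6% Villin WT RING1B. Of 5897 genes with a WT-only PCGF6 peak, 688 had RING1B in AhCre crypts (odds ratio 1.97, adjusted p = 7.40e-37) and 1268 in Villin crypts (2.101, adjusted p = 7.47e-73), by Fisher's exact test. Among these genes, ranked by the strongest WT PCGF6 peak at the gene, which may itself have a KO counterpart, those with RING1B in both lines were led by Tmem109 (452), BC028528 (357), the chromatin gene Hmga1 (338), Acbd4 (305), the kinase gene Cdk2 (181), Zfp653, Ccdc106, the uracil-DNA glycosylase gene Ung, Cdca7l and Lonrf1. Those with RING1B in neither line were Ntn3 (442), Nmi (260), the helix-loop-helix inhibitor gene Id2 (167), Pcna (164), Arap1, Psg25, Git1, Lgals7, Leng8 and Rapgef1. H2AK119ub1 was at 1128 of the genes in AhCre (odds ratio 1.35, adjusted p = 1.20e-13) and 710 in Villin crypts (1.27, adjusted p = 1.07e-06), by Fisher's exact test. CTCF was at 2447 (odds ratio 2.91, adjusted p = 6.34e-225) and RAD21 at 2374 (3.65, adjusted p = 1.21e-306), by Fisher's exact test. With all WT PCGF6 peaks the odds ratios were 4.97 for RING1B in Villin crypts, 4.66 for CTCF and 7.23 for RAD21, and that of H2AK119ub1 in Villin crypts was 1.09 (adjusted p = 0.0633, Fisher's exact test). With the stronger peaks of each list that of RAD21 was 2.36.

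PCGF6 peaks lay at different gene groups in crypts and in ESC. Germline and meiosis genes had PCGF6 in 46 of 63 cases in ESC and 18 in crypts (adjusted p = 4.09e-06), and other developmental transcription factors in 87 of 126 against 17 (adjusted p = 1.59e-16), by the exact McNemar test. Tex19.1 (514), Ddx4 (509) and Sycp2 (372), which act in germ cells, had PCGF6 in ESC and not in crypts, and Zcwpw1 (902 in crypts, 528 in ESC) and Tdrkh (466 and 300) had it in both. Hox genes had PCGF6 in 21 of 39 cases in ESC and 5 in crypts (adjusted p = 5.80e-04, exact McNemar test). The reverse held for ribosomal protein genes, with 70 of 75 in crypts and 8 in ESC (adjusted p = 1.39e-17), and for E2F targets, with 36 of 45 and 15 (adjusted p = 4.36e-06), by the exact McNemar test. Genes of PRC1 and its partners (29 of 37 and 18) and enterocyte markers (10 of 20 and 2) also had PCGF6 more often in crypts (adjusted p = 0.025 each, exact McNemar test). Over all genes, PCGF6 was at 8740 (39.9%) in crypts and 4970 (22.7%) in ESC. The McNemar tests do not allow for this, so a higher count in crypts need not be particular to a list. A peak was present in both crypt genotypes at 35 ribosomal protein genes, 13 E2F targets, 10 genes of the PRC1 list and 3 enterocyte markers. That part of the crypt signal did not go with the gene, and no KO ESC were profiled. Mga, Hdac2, E2f6 and Tfdp1 had PCGF6 in both cell types. Among genes with a WT-only crypt peak, ranked in the same way, the strongest without PCGF6 in ESC were Duoxa1 (186), Id2, Pcna, Psg25, Lgals7, Leng8, Mrpl36, the neighbours Ugt1a7c and Ugt1a9, and Zfp36. The strongest with PCGF6 in ESC were Tmem109, Ntn3, BC028528, Hmga1, Acbd4, Wipf2, Nmi, Kbtbd13, Cdk2 and Zfp653.

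RING1B covered the developmental genes of both cell types and more genes in ESC. Over all genes it was at 1693 (7.74%) in AhCre WT crypts and 3906 (17.8%) in ESC. The McNemar tests do not allow for this, so a higher count in ESC need not be particular to a list. Other developmental transcription factors had it in 120 of 126 cases in ESC and 85 in AhCre crypts (adjusted p = 2.27e-08), germline genes in 37 of 63 and 5 (adjusted p = 4.97e-09), clustered protocadherins in 29 of 57 and 1 (adjusted p = 4.77e-08) and tuft cell markers in 9 of 26 and 2 (adjusted p = 0.0455), by the exact McNemar test. In Villin WT crypts RING1B was at 7 tuft cell markers, so that difference rests on the AhCre list. All 39 Hox genes had it in ESC and 33 in crypts (adjusted p = 0.0769, exact McNemar test). Hox genes and clustered protocadherins lie in clusters and can share a peak, so their p values treat linked genes as independent. Over all genes, 1854 of the 5897 with a WT-only PCGF6 peak in crypts had PCGF6 in ESC (odds ratio 1.89, 95% interval 1.77 to 2.03, p = 8.69e-75, Fisher's exact test), and 5.07 with all WT PCGF6 peaks. Of 1693 genes with RING1B in crypts, 1096 had it in ESC (odds ratio 11.4, 95% interval 10.2 to 12.6), and 17.0 with the stronger peaks of each list. A description line of each ESC sample names the other antibody, and the titles were used here. The ESC lists held 7850 PCGF6 and 5974 RING1B peaks, and the crypt and ESC libraries were not matched in depth.

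**Figure D4:**
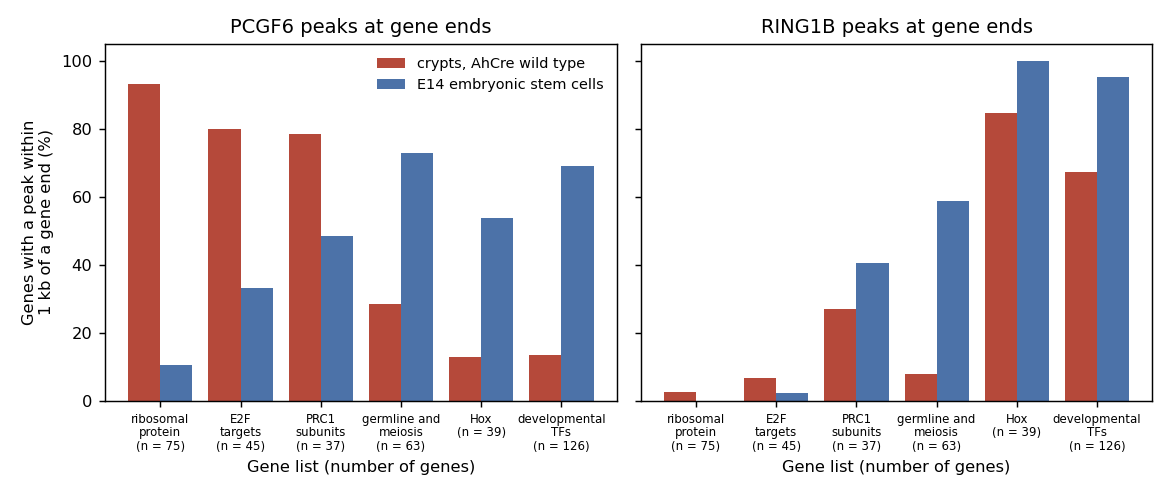
Share of genes of 6 lists with a PCGF6 (left) or RING1B (right) peak within 1 kb of a gene end (vertical axis, percent), in AhCre WT crypts (red) and WT E14 ESC (blue), with 1 library each. PCGF6 is at 70 of 75 ribosomal protein genes in crypts and 8 in ESC, and at 18 and 46 of 63 germline genes. In crypts, 35 of these ribosomal protein genes and 7 of these germline genes had a peak in KO as well.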

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

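Results that differed between the Cre lines are given first, and 3 patterns are then weighed. The tests chosen only after the result was seen are those of CTCF at remaining PCGF6 peaks, of 20 score strata for RING1B and RAD21, of loss at PCGF6 peaks present in the KO list, and of the scores of H2AK119ub1 KO-only peaks. The Villin odds ratio of RING1B loss at WT-only PCGF6 peaks was 0.802 times that of AhCre (Woolf chi-square test, adjusted p = 0.0431), and with all WT PCGF6 peaks 1.27 times (adjusted p = 0.0339). For H2AK119ub1 loss, the Woolf chi-square test gave factors of 1.74 (adjusted p = 1.16e-08) and 1.63 (adjusted p = 1.03e-08). The KO to WT ratio of H2AK119ub1 peak numbers was 1.22 in AhCre and 0.883 in Villin crypts, a difference that was not tested.

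The KO list held 4779 PCGF6 peaks, nearly all at WT sites. A KO library with evenly lower yield would lose peaks of like score alike, but PCGF6 peaks with H2AK119ub1 were lost more often than those without (odds ratio 2.76 over 20 score strata, 95% interval 2.37 to 3.20), which argues against this as the whole cause. Sites that give signal without PCGF6, such as open or CTCF-bound chromatin, are a candidate explanation: 40.2% of the remaining peaks had CTCF against 29.3% of lost ones (odds ratio at equal score 1.29, 1.18 to 1.42). Remaining peaks also had ESC PCGF6 more often (42.98% against 17.17% of lost ones) and Villin WT RING1B more often (27.54% against 11.57%). H2AK119ub1 went the other way. Those shares were not taken at equal score, so they cannot tell such sites from residual PCGF6. PCGF6 left in an even share of cells that escaped recombination makes the same prediction as evenly lower yield. The odds ratio of 2.76 thus argues against it as the whole cause too. Escape that differed between cell types stays open and was not tested.

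RING1B and RAD21 were lost more often at WT PCGF6 peaks than at peaks without PCGF6. Weaker peaks dropping below the score limit first would leave no difference at equal score, but the odds ratios over 20 strata were 1.78 (RING1B AhCre), 2.33 (RING1B Villin) and 1.88 (RAD21). An even loss of enrichment over gene ends would leave no difference among peaks at gene ends, where the odds ratios were 1.602, 2.49 and 1.61. Promoters were not told apart from other gene ends, so this cannot decide on a loss confined to promoters or to some of them. Signal in WT libraries at sites that give PCGF6 signal without PCGF6 could contribute, since loss was more frequent where the PCGF6 peak was also in the KO list, with odds ratios at equal PCGF6 score of 1.61 (95% interval 1.11 to 2.33), 2.44 (1.93 to 3.09) and 1.17 (1.012 to 1.36). The scores of the RING1B and RAD21 peaks themselves were not held equal there. Their medians were lower where the PCGF6 peak was also in the KO list (14.8 against 15.4, 14.5 against 14.7 and 21.8 against 23.7). Recruitment by PCGF6 stays open. As it needs, WT-only PCGF6 sites had more loss than peaks without PCGF6 (1.38, 1.28 and 2.00 at equal score). That comparison was chosen after the result was seen. In AhCre crypts loss was still higher where a PCGF6 peak remained in the KO list. Such a peak shows only that signal still passed the score limit, and scores are not scaled between libraries. How far PCGF6 fell at these sites is unknown, so their higher loss cannot decide on recruitment. PCGF6 was not profiled in Villin crypts, so for RING1B Villin and RAD21 it is unknown where signal remained.

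H2AK119ub1 peak numbers went up in AhCre and down in Villin KO crypts. Broad domains split by gaps of up to 2 kb would not raise the number of regions merged within 2 kb, whose KO to WT ratio in AhCre crypts was 1.19. Wider gaps would raise it, so splitting is not excluded. Covered length had a lower ratio (1.12) than peak number, and median peak width was 1428 bp in WT and 1319 bp in KO. Depth or yield of single libraries stays open: 28.1% of the AhCre KO-only peaks scored above the median of their list, but unmatched peaks were mostly weak in every crypt list, so this share decides nothing. A biological difference between the Cre lines stays open and was not tested.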

How the results depend on the processing

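The alternatives combining all WT PCGF6 peaks with score strata, and those against peaks without PCGF6, were chosen only after the result was seen. Of 157 values under alternatives, 121 were the same, 21 moved, 5 were weaker, 4 stronger and 6 reversed. Among peaks scoring above their list's median, WT-only and KO-only counts were 4443 and 11 for PCGF6, 228 and 33 for RING1B AhCre, 771 and 34 for RING1B Villin, 832 and 1860 for H2AK119ub1 AhCre, 790 and 444 for H2AK119ub1 Villin, 5 and 6 for CTCF and 210 and 62 for RAD21. With lists of equal length they were 1513 and 1446 for PCGF6, 502 and 432 for RING1B AhCre, 861 and 730 for RING1B Villin, and 2806 and 2692 for RAD21, near equal by construction. For loss at PCGF6 sites, odds ratios were 0.891 for RING1B Villin within 1 kb (adjusted p = 0.0811, Fisher's exact test) and 1.48 for CTCF peaks above the median (adjusted p = 0.579, Fisher's exact test, 5 lost peaks). Over score quintiles they were 0.998 for RING1B AhCre, reversed from a value that passed no test, and 0.871 for H2AK119ub1 Villin (95% interval 0.751 to 1.012). With all WT PCGF6 peaks RING1B gave 1.87 in AhCre and 2.37 in Villin crypts, the latter reversed, and with score quintiles as well 1.77 and 2.36, with H2AK119ub1 Villin at 1.03. Against peaks without PCGF6, with those on PCGF6 peaks of the KO list left out of both groups, WT-only sites gave 1.49 for RING1B AhCre and 1.55 for RING1B Villin, the latter reversed, and over score quintiles 1.38, 1.28 and, for H2AK119ub1 Villin, 0.906 (95% interval 0.779 to 1.053). The cause of these shifts was not tested. Co-occupancy of PCGF6 and H2AK119ub1 in Villin crypts was 1.09 with all WT PCGF6 peaks (adjusted p = 0.0633, Fisher's exact test). Gene list calls numbered 94, 95 with a 2.5 kb window and 74 with peaks above the median. Of 100 named gene calls, 93 held with a 2.5 kb window, 79 with 500 bp, 99 with matching within 1 kb and 100 with 50% overlap. Motif tests and strata of CpG content were not run, because no genome sequence was used here.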

Other observations

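The tests of RING1B peaks by H2AK119ub1 and of RAD21 peaks by CTCF were chosen only after the result was seen. RING1B peaks without H2AK119ub1 were lost in 63.8% of 757 cases in AhCre crypts against 34.4% of 1611 with it (odds ratio 3.36, 2.07 over score strata), and in 72.2% of 2547 against 31.5% of 1856 in Villin crypts (5.64, and 3.53 over strata). Without H2AK119ub1, the shares lost were 69.7% and 76.1% with PCGF6 and 52.0% and 59.6% without it. With H2AK119ub1 they were 38.2% and 31.3% with PCGF6 and 31.3% and 31.7% without it. RING1B peaks at Hox genes and at developmental factors such as Otx1 and Pax6 had H2AK119ub1 and were mostly found in both genotypes. Absence of the mark thus went with more loss whether or not PCGF6 was there. The shares split by PCGF6 were not taken at equal score, and no comparison was made at equal width. Peaks with the mark were wider (median 1520 against 787 bp in AhCre and 1305 against 680 bp in Villin crypts). A wider peak can more easily overlap a KO peak by 1 bp, so width may account for part of the difference. Whether the difference by PCGF6 itself depended on the mark was not tested.

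RAD21 peaks without CTCF were lost in 78.6% of 2653 cases against 16.4% of 18000 with it (odds ratio 18.7, 3.88 over score strata), and 66.5% of the former had PCGF6 against 23.3% of the latter. Among RAD21 peaks without CTCF the share lost was 77.9% with PCGF6 and 80.0% without it, and among those with CTCF it was 20.6% (exact 95% interval 19.4 to 21.9) and 15.1% (14.5 to 15.7). The loss of RAD21 at PCGF6 peaks (1.88 at equal score) could thus partly reflect that CTCF-free RAD21 peaks sit at PCGF6 sites, but among peaks with CTCF a difference by PCGF6 was left.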
